A study of Homo sapiens with 2 samples.

How the data were processed

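HCT116, an established line of human colorectal carcinoma cells, was studied by chromatin immunoprecipitation and sequencing. Per the labels, 1 library came from chromatin precipitated with an anti-RUNX2 antibody and 1 from input DNA. The chromatin was sheared to fragments of about 200 bp and sequenced on an Illumina Genome Analyzer IIx, per the labels' protocols. The precipitate with control immunoglobulin G that the protocols mention was not analysed here.

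The analysis started from 1 deposited peak list. Per the file headers, the authors called peaks with MACS 2.1.0.20150420 on uniquely mapped, deduplicated tags of the RUNX2 library against the input library. The caller ran without a fragment model, extended tags to 200 bp, searched for summits and kept peaks at p of 0.01 or below, per the file headers. It scaled the larger library to the smaller and took the local background from windows of 1000 and 10000 bp. The effective genome size was set to 3099750718 bp. The aligner is not given in the sources used here. The tags were 50 bp long. The header recorded 16786264 tags kept of 16802917 for RUNX2 and 17784318 kept of 17798426 for input. At that depth a base of the genome carried 1.08 extended RUNX2 fragments on average.

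The deposited pileup is a coverage signal, the number of extended RUNX2 fragments over the summit, and was not scaled because the RUNX2 library was the smaller. The deposited fold enrichment is the ratio of the pileup plus 1 to the local input background plus 1. The local background was computed back from these values, and its lowest value, 1.08, equalled the average coverage of the genome. The deposited −log10 p is the caller's value at the summit. The names of this column and of another were lost in the file. The later column was read as −log10 q from its place in the caller's usual order. A header line states that q was not calculated, yet the column held values between 0 and 20.7, and these were used as q. Scores and folds are the authors' own and served only to describe and rank peaks within the list.

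The submitters' processing notes name the build mm9, a mouse assembly, while the list held chromosomes 1 to 22, X and Y and human scaffolds. Of these peaks, 24 lay on KI270 scaffolds, names that came with GRCh38, so the coordinates were read as GRCh38. Peak positions are printed as deposited. Gene names and distances came from the RefSeq gene table of GRCh38.p14, with 20037 protein-coding genes. All members of the 17 gene lists were found in it. The table gives gene spans without strand, so transcription start sites could not be told from the other ends. Both ends of each span therefore replaced the start site in every test, a change made after the data were examined. Exons, introns and untranslated regions were not analysed here. Neither was the RUNX motif, which needs genome sequence.

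With 1 library of each kind there was no replicate, and no p-value here compares samples. Each test describes this 1 list, with peaks or genes as the items. The share of peak centres within 1 kb of a gene end was compared with the share of sequence so placed by a two-sided exact binomial test, with exact 95% intervals that cover counting error only. The same peaks moved by 50 kb gave a further control by McNemar's exact test, added after the data were examined. Sequence length included assembly gaps, and it counted X and Y in full although few peaks lay on X. Median folds were compared by a two-sided permutation test with 100000 resamples. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests on members with a peak centre within 10 kb of either end, with Benjamini-Hochberg adjustment over 17 lists. As an alternative, 10000 random lists were drawn from the 200 genes nearest in length to each member.

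The gene lists, the tests and the rule for named genes were set before the data were examined. The rule took the 3 genes recalled from the study, the core-binding factor genes, the genes nearest to the 10 peaks of highest fold, the same for peaks within 1 kb of a gene end, up to 4 members of each other list with the highest-fold peak, and the 5 genes with the most peaks. Of the genes it took, 1 is not reported here. As recalled, the study's 3 genes were chosen by its authors on these samples, which was not checked here. Alternatives were stricter thresholds, peaks of autosomes and X alone, peaks within 1 kb merged, other distances, other scores, whole genes and matched lists.

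Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. The tests were tested on simulated data with 23154 peaks and the 20037 genes. Random peaks were spread evenly over the full length of all chromosomes, unlike the observed peaks, which were few on X. These lists therefore do not show how the binomial test behaves on the observed peaks. Of 20 random peak lists, 2 were called near gene ends. Of 340 random tests of gene lists, 3 were called. With 5% of peaks placed at gene ends, 7.13% were found there against 7.24% expected. When 50% of members were given a peak, all 14 lists with at least 20 members were called. The median test called 5 of 100 unshifted sets and 100 of 100 sets shifted by 0.2. Those simulated values were continuous, whereas many peak folds were tied, so this does not give the power of the test on the peaks.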

Results

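RUNX2, a Runt-domain transcription factor that binds DNA together with its partner CBFβ, was profiled in HCT116 colorectal carcinoma cells. The data comprised 1 RUNX2 library of 16786264 tags and 1 input library of 17784318 tags. The stated purpose was to find genes under direct transcriptional control by RUNX2. The single comparison was therefore the RUNX2 library against input, and its output was the authors' list of peaks. There were no replicates, so no value below carries an error between samples.

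The list held 23154 peaks, most of them at the low end of what the caller can report. The number of RUNX2 fragments over the summit had a median of 5 and lay between 4 and 7 for 21653 peaks (93.5%). Fold enrichment over the local background ran from 1.80 to 12.0 with a median of 2.88 and quartiles of 2.63 and 3.28. Peak width had a median of 202 bp, and 11427 peaks (49.4%) had the minimum of 200 bp. After the caller's adjustment, 41 peaks passed q of 0.05, which is 0.177% of the list (exact 95% interval 0.127 to 0.240%), and 19 passed q of 0.01. The adjusted value was q = 1 for 12954 peaks (55.9%).

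**Figure D1:**
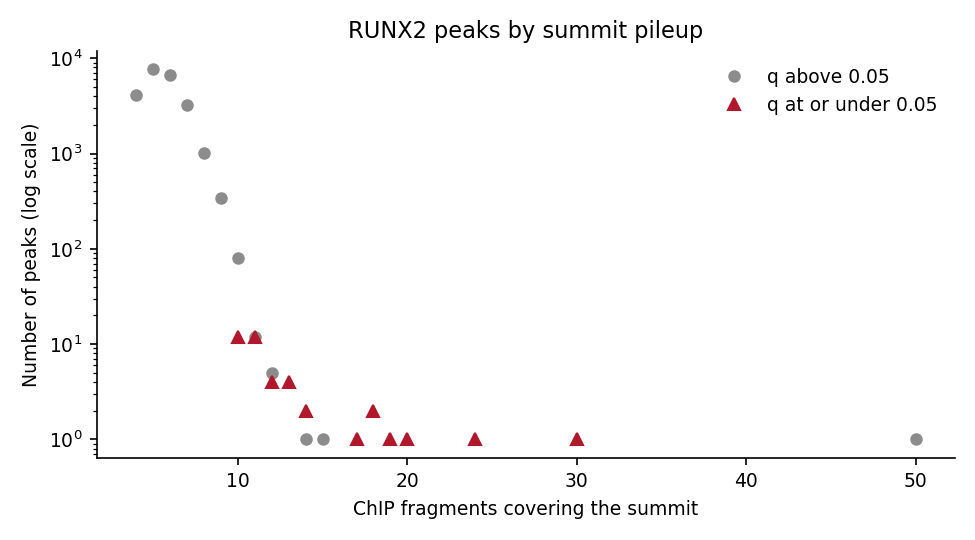
Number of RUNX2 peaks (vertical log axis) by the number of RUNX2 fragments covering the summit (horizontal axis), with peaks above and at or under q of 0.05 shown apart. Most peaks lie at 4 to 7 fragments, and the 41 peaks at or under q of 0.05 begin at 10.

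The 10 peaks of highest fold lay at least 6.45 kb from the nearest gene end. The highest fold was found on chromosome 1 at 34247268 to 34247693, where 24 fragments gave a 12.0-fold enrichment (q = 4.8e-18), 28.3 kb outside C1orf94. A peak on chromosome 11 at 11246434 to 11247194 had 30 fragments and the same 12.0-fold enrichment (q = 1.84e-21), 24.1 kb outside GALNT18, which encodes an enzyme of the family that starts O-linked glycosylation. A further region, on chromosome 15 at 85896227 to 85897528, was the widest of the list at 1302 bp, with 20 fragments and a 9.20-fold enrichment, 102 kb from KLHL25. The peak on chromosome 12 at 124092780 to 124093488 reached 8.55-fold inside ZNF664-RFLNA, a readthrough locus. DNAJB6, a co-chaperone gene, was nearest to a peak of 6.67-fold at a distance of 44.0 kb.

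The other 5 of the 10 highest folds ranged from 5.84 to 6.24. Their nearest genes were SHPRH, a ubiquitin ligase gene, at 7.47 kb, SNTG1 at 6.45 kb, the homeobox gene BARX1 at 14.9 kb, LRATD1 at 93.1 kb and LOC124902561 at 205 kb. Of the 40 peaks with q at or under 0.05 on assembled chromosomes, 16 lay within the span of a protein-coding gene and 24 outside. Those inside included peaks in DACH1, TRIO, IL1R2 and JAK1, and a peak 46.2 kb from EPCAM, an epithelial adhesion gene, was among those outside. These 5 genes were chosen after their values were seen.

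Next, the 3 genes recalled as those the study followed as RUNX2 targets were examined. SPP1 encodes osteopontin, NIBAN1 (FAM129A) a stress-response protein and UPP1 a uridine phosphorylase. Peaks were counted over the gene and 10 kb on each side. SPP1 had 1 peak, 8.27 kb beyond an end of the gene on chromosome 4 at 87991578 to 87991777, with 5 fragments and a 2.58-fold enrichment (q = 1). NIBAN1 had 2 peaks inside the gene on chromosome 1, at 184836070 to 184836348 with 7 fragments and 3.84-fold (q = 0.675), and at 184937834 to 184938083 with 4 fragments and 2.40-fold (q = 1). UPP1 had 1 peak inside the gene on chromosome 7 at 48099889 to 48100092, with 4 fragments and a 2.34-fold enrichment (q = 1).

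Other genes of similar length often had as many peaks. Counting the gene and 10 kb on each side, 20.5% of the 200 genes nearest in length to SPP1 had as many peaks, 49% for NIBAN1 and 27.5% for UPP1. SPP1 and UPP1, 2 of the 3 genes, had a peak within 10 kb of an end, against 23.4% of other genes (Fisher's exact p = 0.139, adjusted p = 0.513). As the authors are recalled to have chosen these genes on the same samples, the count is not independent evidence. None of the 4 peaks passed q of 0.05, and 1, in NIBAN1, was among the 11577 peaks of highest fold.

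**Figure D2:**
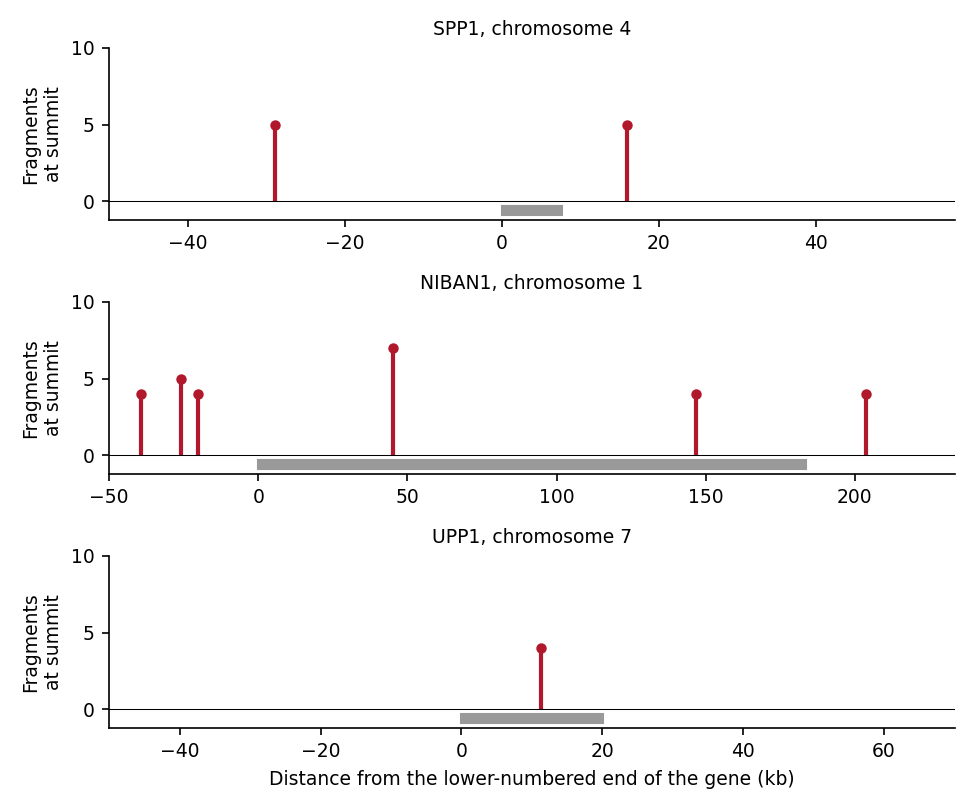
Peaks around SPP1, NIBAN1 and UPP1. The horizontal axis gives the distance in kb from the lower-numbered end of the gene, the grey bar is the gene span, and each red stem is a peak whose height is the number of RUNX2 fragments at its summit. Peaks up to 50 kb to each side are drawn, beyond the 10 kb counted in the text, and the highest, inside NIBAN1, has 7 fragments.

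The core-binding factor genes, which encode the RUNX proteins, CBFβ and related corepressors, had no peak within 10 kb of an end (0 of 7, exact upper limit 41.0%, Fisher's exact p = 0.211, adjusted p = 0.513). Inside the genes, CBFB had 2 peaks of 3.84-fold and 2.88-fold, RUNX2 itself 2 peaks of 3.07-fold and 2.21-fold, and CBFA2T2 2 peaks of up to 3.59-fold. RUNX1, RUNX3 and RUNX1T1 had 1 peak each, of 2.65-fold, 2.67-fold and 2.79-fold, and CBFA2T3 had 0. None of these peaks passed q of 0.05. Counting the gene and 10 kb on each side, 6 of 7 genes had a peak (85.7%), against 68.7% for genes of matched length (matched permutation p = 0.589).

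Peaks were then placed against gene ends. Within 1 kb of an end of a protein-coding gene lay 565 of 23125 peaks, or 2.44% (exact 95% interval 2.25 to 2.65%), against 2.36% of the sequence (ratio 1.04, 0.953 to 1.12, exact binomial p = 0.398). The same peaks moved by 50 or 100 kb gave 2.49 to 2.65%. At 5 kb the share was 10.4% against 9.94% of the sequence (exact binomial p = 0.0339), but moved peaks gave 10.7 to 11.2%. At 10 kb it was 18.1% against 17.1% (exact binomial p = 2.35e-05), and moved peaks gave 18.6 to 19.1%. At each of these distances the share lay below that of every set of moved peaks. McNemar's test was run only against a move of 50 kb to higher positions, which gave the lowest moved share at 5 and 10 kb. There neither share passed the threshold (McNemar's exact p = 0.169 and 0.162), and the larger differences from the other moves were not tested. Protein-coding gene spans held 45.8% of the peaks against 40.9% of the sequence (exact binomial p = 8.38e-51), and between 45.7 and 46.4% of moved peaks.

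Among peaks within 1 kb of a gene end, the highest folds were 4.80 at DUSP12, a phosphatase gene, and at the embryonic globin gene HBE1 (q = 0.107 for both). PGLYRP3, a peptidoglycan recognition gene, followed with 4.57 and the globin gene HBA2 with 4.50 from 12 fragments (q = 0.0614). RIPOR3, NEU1, MT1M and DHDH had 4.32-fold peaks and PDE6A and APOC2 4.22-fold peaks. Of the 40 peaks at or under q of 0.05, 0 lay within 1 kb of a gene end (exact upper limit 8.81%) and 6 within 10 kb. Within 5 kb lay 0 of 40, against 9.94% of the sequence (exact binomial p = 0.0301), and against the same peaks moved by 50 kb McNemar's exact p was 0.5. The median fold was 2.88 both for the 565 peaks within 1 kb of a gene end and for the 22560 others (difference 0). Many peaks share the same fold, and a difference of 0 can never pass the permutation test, so equal strength was not shown. The median pileup was 6 fragments near gene ends and 5 away from them (permutation p = 0.322).

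Gene groups relevant to RUNX2, to the tumour and to other cell types were compared with all other protein-coding genes. Of all 20037 such genes, 4693 (23.4%) had a peak within 10 kb of an end. None of the 17 lists differed after adjustment (lowest adjusted p = 0.44, Fisher's exact test), and 1 had an unadjusted p under 0.05. That list, the ribosomal proteins, had 9 of 73 members with a peak (12.3%, Fisher's exact p = 0.0259, adjusted p = 0.44), among them RPL18 and RPL13A, and genes of matched length had 18.0%.

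The folds given for members of the lists are those of their strongest peak within 10 kb of an end. No member of any of the 17 lists had a peak within that distance that passed q of 0.05. Osteoblast and cartilage genes that textbooks list as RUNX2 targets had a peak at 6 of 24 members. SP7, the osterix gene of bone formation, had a 4.32-fold peak and TNFRSF11B, encoding osteoprotegerin, a 3.65-fold peak, while HAS2 and TGFBR1 had weaker ones. The AP-1 family had 3 of 17 members with a peak, MAFG, ATF2 and MAFK, with folds between 2.81 and 2.90. Wnt pathway genes had 11 of 47, led by the receptor genes FZD8 (3.62-fold), FZD1 and FZD6 (3.53-fold each) and by EPHB2 (3.45-fold). TGF-β and BMP pathway genes had 9 of 39, with ACVR1B at 3.81-fold, SMAD9 at 3.36-fold, and ACVR1 and SKIL at 3.28-fold.

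YAP and TEAD pathway genes had 5 of 30 members with a peak, the strongest at MOB1A (3.84-fold) and AMOTL1 (3.65-fold), followed by PTPN14 and WWTR1. Genes of invasion and the epithelial-mesenchymal transition had 8 of 44, including LAMA3 (3.59-fold), ITGB4 (3.41-fold), CDH2 (3.36-fold) and CXCR4 (3.25-fold). Angiogenesis factors had 2 of 23, EDN1 (2.58-fold) and CXCL8 (2.40-fold). Cell cycle and growth genes had 14 of 44, among them ERBB2 (3.56-fold), CCNB1, CCNE1 and MCM2. Apoptosis genes had 3 of 27, BAX (4.32-fold, a peak shared with DHDH), BCL2 (3.72-fold) and CASP9 (3.59-fold). Nucleoside metabolism genes had 7 of 27, with ADA (3.07-fold) and UPP2, DHODH and TYMS below it within that distance, while a 3.85-fold peak lay farther inside UPP2.

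Intestinal epithelium genes, the tissue of origin of the line, had 11 of 42 members with a peak (26.2%), among them GPA33 (3.42-fold), GATA6, KRT19 and TSPAN8. Lists of cell types absent from the line were measured alike. Blood cell genes had 10 of 42 (23.8%), led by HBA1 and HBA2, which share a 4.50-fold peak, with ITGAM and SPI1. Neuron genes had 11 of 30 (36.7%), led by GABRB2 and NEFM (3.84-fold each) with SNAP25, and muscle genes 8 of 28 (28.6%), led by TNNI2 (3.62-fold) with NEB, CASQ1 and TTN. When a peak anywhere in the gene or within 10 kb counted, 2 lists passed Fisher's exact test, ribosomal proteins (12.3% against 37.5%, adjusted p = 4.17e-05) and neuron genes (66.7% against 37.4%, adjusted p = 0.0162). Neither passed against random lists of matched length (lowest adjusted permutation p = 1).

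**Figure D3:**
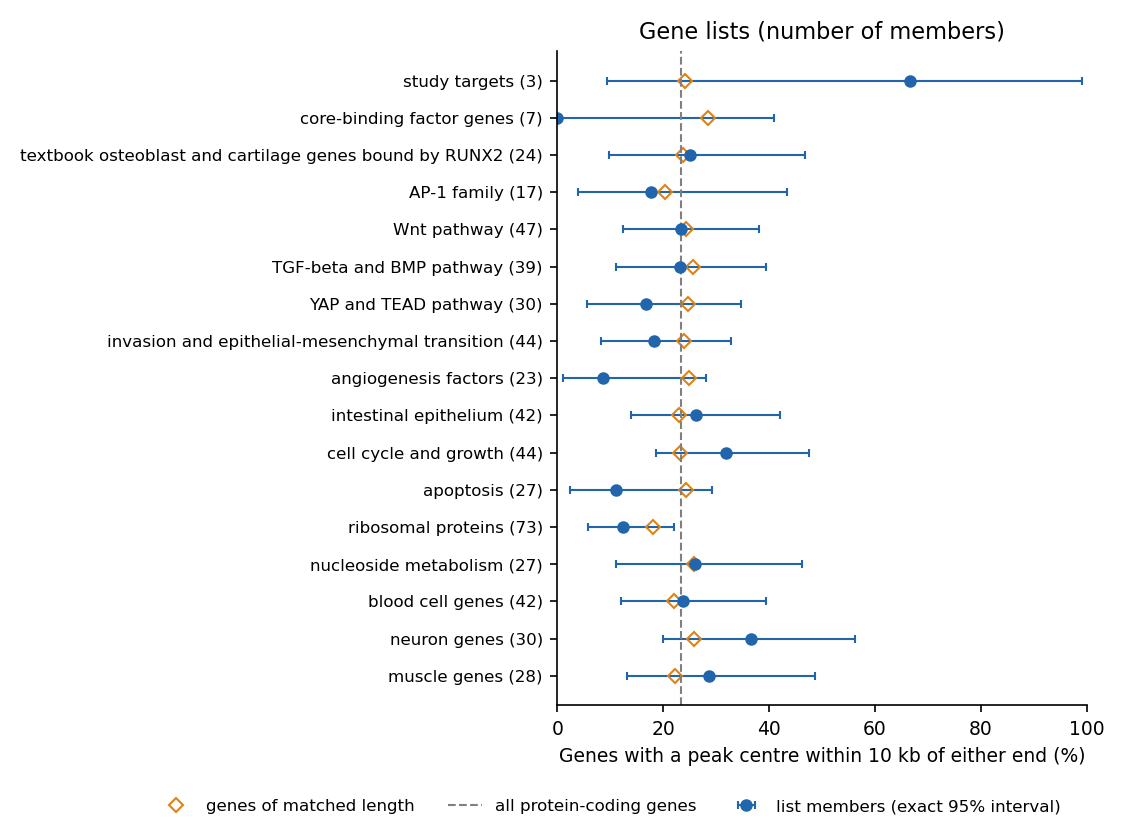
Percent of each list's members with a peak centre within 10 kb of either gene end (blue points, exact 95% intervals), for genes of matched length (open diamonds) and for all protein-coding genes (dashed line, 23.4%). The interval of ribosomal proteins alone leaves out the dashed line, and no list differed after adjustment.

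The genes with the most peaks were long ones. EYS had 23 peaks, CTNNA3 and PDE4D 19 each, and CNTN5 and GPHN 18 each. Across genes, which are not independent replicates, gene length and peak number correlated with a Spearman's rho of 0.493. Peaks were counted over the gene and 10 kb on each side, so scattered peaks alone would give a positive correlation.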

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

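The start site was replaced by both gene ends, and the limit of q at 0.05, moved peaks and the header's genome size were added, after the data were examined. The number of peaks fell from 23154 to 11577 at the higher folds by construction, to 41 at q of 0.05 and to 19 at q of 0.01, and stayed within 1.5 times on autosomes and X or with close peaks merged. The share near gene ends passed its threshold at 5 kb (10.4%, exact binomial p = 0.0339) and, outside the listed alternatives, at 10 kb (18.1%, exact binomial p = 2.35e-05). Moved peaks gave higher shares still, 10.7 to 11.2% and 18.6 to 19.1%. The excess over the sequence was thus not particular to the peaks' own positions, and its cause was not tested. The alternatives that kept the distance of 1 kb kept their side of the threshold. Lists passing numbered 2 when whole genes counted and 0 with lists of matched length. The median fold near and away from gene ends gave no value at q of 0.05 or 0.01, as no such peak lay within 1 kb of an end. Elsewhere every difference in median fold was 0, which cannot pass a threshold. The median −log10 p also differed by 0, and the pileup medians, 6 and 5, passed none (permutation p = 0.322). Among single lists and genes, 328 values kept their side or moved little, 178 moved and 2 newly passed, both with whole genes. The motif alternatives were not run. No paired analysis was possible because there was 1 library of each kind. Low depth and weak enrichment were not told apart as sources of the low pileups, at 4 to 7 fragments for 93.5% of peaks.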

Other observations

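Every test below was chosen after the result it bears on, or part of it, had been seen, except the comparison of close peaks with random placement.

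Gene families outside the lists gave no group that stood apart. Of 20 families, chosen after the lists had been examined, 0 passed adjustment (lowest adjusted p = 0.20, Fisher's exact test) and 2 had an unadjusted p under 0.05. Taste receptors had a peak within 10 kb of an end at 1 of 28 genes (Fisher's exact p = 0.0117) and forkhead genes at 5 of 52 (p = 0.0202). Against genes of matched length these gave permutation p of 0.109 and 0.107, and the lowest was 0.0246, for histone genes (24.1% against 14.4%, adjusted p = 0.458). Olfactory receptors, silent in most tissues, had 81 of 392 (matched permutation p = 0.112), and HOX genes 7 of 40 (matched permutation p = 1). The highest pileup of the list, 50 fragments on chromosome 16 at 34586074 to 34586279, had the lowest fold, 1.80, over a local background of 27.4 (q = 0.675). Across 22 autosomes, gene density and peak density gave Pearson's r of -0.18 (permutation p = 0.42) and Spearman's rho of -0.34 (permutation p = 0.117, adjusted p = 0.235 over 2 relations). Without chromosomes 17 and 19, r was -0.38 (permutation p = 0.0961).

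Chromosome X held 119 peaks, 0.763 per Mb, against 8.01 per Mb on the autosomes, a ratio of 10.5 (95% interval 8.77 to 12.7). A higher input background on X is argued against, since 96.6% of X peaks sat at the lowest possible background, compared with 32.0% on autosomes (Fisher's exact p = 3.33e-51). A candidate explanation is fewer copies of X under a threshold set for the whole genome. The part of X between PLCXD1 and CD99, shared with Y, had 2.17 times the density of the rest (0.581 to 5.70, p = 0.12), by an exact binomial test where a Fisher's exact test had been foreseen. Fewer copies would lower the input on X too, so the 96.6% at the lowest background goes with this explanation but does not test it. The shared part held 4 peaks, 1.62 per Mb, below the 8.01 per Mb of the autosomes. The comparison presumes that this part had more copies than the rest of X, which was not checked. Of 23125 peaks on assembled chromosomes including Y, 23124 lay on the autosomes and X. With only 4 peaks and that premise unchecked, the question stays open, and no biological explanation was tested.

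Peaks were not concentrated near gene ends. Another genome build is argued against by the 24 peaks on KI270 scaffolds. Background fluctuations that pass a permissive threshold stay open as the cause. By the caller's adjustment 41 of 23154 peaks (0.177%) passed q of 0.05, so most peaks were not told from background one by one. The 2315 strongest peaks lay within 10 kb of an end 1.02 times as often as the 50% of peaks with the lowest folds (18.4% and 18.1%, ratio interval 0.926 to 1.12, Fisher's exact p = 0.723). This ratio met the prediction written for background fluctuations. The reading was changed to open after its value was known. Dilution of start sites by the other ends stays open: start sites would be enriched at most 1.25 times if the other ends lay at expectation, but up to 2.25 times if these held no peak. Binding of RUNX2 far from genes would leave the strongest peaks no nearer to gene ends either, so it cannot be told apart from background here.

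Within 2 kb of another peak lay 1122 autosomal peaks, 1.40 times the mean of 1000 random placements within bins of 1 Mb (800, central 95% 723 to 878, permutation p = 0.000999, the smallest these can give). Several summits within 1 called region are argued against, as 1 of 569 close pairs (0.176%) shared its start and end. Crowding by stretches of 20 kb or more without unique tags is too, as pairs 0.2 to 2.2 kb apart were 1.47 times as many as pairs 20 to 22 kb apart (1.30 to 1.67). Raised input coverage is as well, as the share above the lowest background was 62.7% for close peaks and 68.3% for others (difference -5.66 percentage points, -8.56 to -2.77). Regions broken into neighbouring calls, or shorter stretches without unique tags, could still add close peaks and were not tested, and no biological explanation was tested.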
